A study of Danio rerio with 20 samples.

How the data were processed

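The series measured RNA from zebrafish larvae by RNA sequencing, in 20 libraries that fall into 5 groups of 4. The larvae were exposed to citalopram, a selective serotonin reuptake inhibitor, at 10 or 1000 µg/L, to ifosfamide, an alkylating anticancer drug, at 1 or 100 µg/L, or belonged to the group named ERM. The labels do not spell ERM out, and the treatment entry of that group carries a concentration with no compound beside it. The design text lists ERM first among the groups and names no drug directly after it, so ERM was taken as the reference without either drug. Per the labels, 5 beakers were exposed per treatment and 4 of them were sequenced, and each library was treated as an independent beaker. The age of the larvae and the length of exposure are not stated in the labels. RNA was extracted with TRIzol, poly(A) RNA was selected, and strand-specific libraries were sequenced by a commercial provider.

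The submitters' processing notes name fastp, HISAT2, featureCounts and DESeq2, with neither versions nor roles, and the GRCz11 genome build. The authors deposited a table of FPKM, fragments scaled to gene length and library depth, for 38718 gene models with their positions and lengths. Of these, 31901 carried an Ensembl identifier and 6817 did not. Symbols, positions and lengths were used as the table gives them. Each FPKM was multiplied by its gene length and divided by the smallest step of its library, and 100% of the values above 0 came within 0.01 of a whole read, with 0 values more than 1e-06 away. The read counts recovered this way gave the depth of each library. The scaling between libraries equalled median-of-ratios size factors, with 0 libraries deviating by over 1e-06, so the FPKM values were compared between libraries as deposited. Depth ranged from 10699800 to 17311000 recovered reads per library.

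Differences between groups were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend, 1 coefficient per group and 15 residual degrees of freedom. All 20 libraries entered the model, so that every group shared an estimate of each gene's spread. The spread between replicates was unequal. Chi-square per degree of freedom of recovered reads was 30.2 to 160 between libraries of citalopram 1000 µg/L and 7.15 to 37.7 within the other groups. The shared estimate may thus be too large for comparisons without citalopram 1000 µg/L and too small for those with it. Counts at an unadjusted p under 0.05 need not follow the number given by chance. The 19723 gene models with a mean FPKM of at least 1 over all libraries were tested. They comprised 15822 protein-coding genes and 3294 gene models without an Ensembl identifier. Each drug dose was compared with ERM and the doses of each drug with each other, which made 6 comparisons, and a moderated F-test over the 4 comparisons against ERM asked whether any group differed. Tests were two-sided, p was adjusted by the Benjamini-Hochberg method within each comparison, and adjusted p under 0.05 counted as past the threshold. Fold changes are differences of group means of log2(FPKM + 1), given with their standard error from the model. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

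The gene lists, the comparisons, the tests, the rule for named genes and most alternatives were set before the data were examined. The 43 gene lists covered drug targets, stress responses, metabolism, tissues and cell types. Of these, 42 had at least 5 tested members and 1 was too small to test. Lists were tested with limma's camera, with the correlation between genes estimated from the data, and then with camera at a preset correlation of 0.01 and with fry. For each list the members past the threshold were also counted with p adjusted over the list alone. The rule for named genes took, in each comparison and direction, up to 12 genes past the threshold whose groups did not overlap, or else the 5 genes with the smallest p. It added up to 4 members of any list with at least 2 members past the threshold, and 18 genes fixed for their known link to the drugs. Placeholder symbols were left out of that rule. The other genes named were chosen after their values were seen.

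For each comparison, all 35 splits of the 8 libraries into 4 and 4 were run through the same model, and 100 random regroupings were run for the test over all groups. The alternatives covered the pseudocount, the filter, the scaling, the weighting of libraries, a replicate block, the groups in the model, the genes included, a minimum fold change and each library left out in turn. After the data were seen, voom on recovered reads, scaling to total reads, 2 corrections for gene length, a model without library C of citalopram 1000 µg/L, summed values of the fast myosin genes and each group against the mean of the other 4 were added. The model was checked on simulated data for all libraries, drawn with independent noise from each gene's mean and residual SD over all groups. In each of 10 runs, 200 of 19723 genes were changed at citalopram 1000 µg/L, chosen among those with higher mean levels. The model called 57% of the genes changed by 1 on the log2 scale, 97.8% of those changed by 2 and 6.63% of those changed by 0.5, with a mean of 5.3 false calls per run. The simulation held no correlation between genes and no library that stood apart, so these rates need not hold for the real comparison.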

Results

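Expression was measured in 20 libraries of zebrafish larvae, 4 per group, after exposure to citalopram or ifosfamide at 2 doses each or in the ERM reference. Recovered reads per library ranged from 12049100 to 13897700 in ERM, from 11259500 to 14364700 at citalopram 10 µg/L, from 11725600 to 17311000 at citalopram 1000 µg/L, from 11124300 to 13590800 at ifosfamide 1 µg/L and from 10699800 to 12495100 at ifosfamide 100 µg/L. Correlations of log2(FPKM + 1) between libraries of the same group ranged from 0.844 to 0.978. Over all pairs of libraries, within and across groups, the lowest was 0.916 once library C of citalopram 1000 µg/L was left out. That library had 25952 gene models above 0, against 28913 to 30110 in the other 19 libraries, and its signal fell with gene length by a slope of -0.324 (log2 per doubling of length). Library D of the same dose had the highest length slope of all libraries (0.133). Its deviation from the rest of its group was the next largest after library C (SD over genes 0.650 against 0.865).

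**Figure D1:**
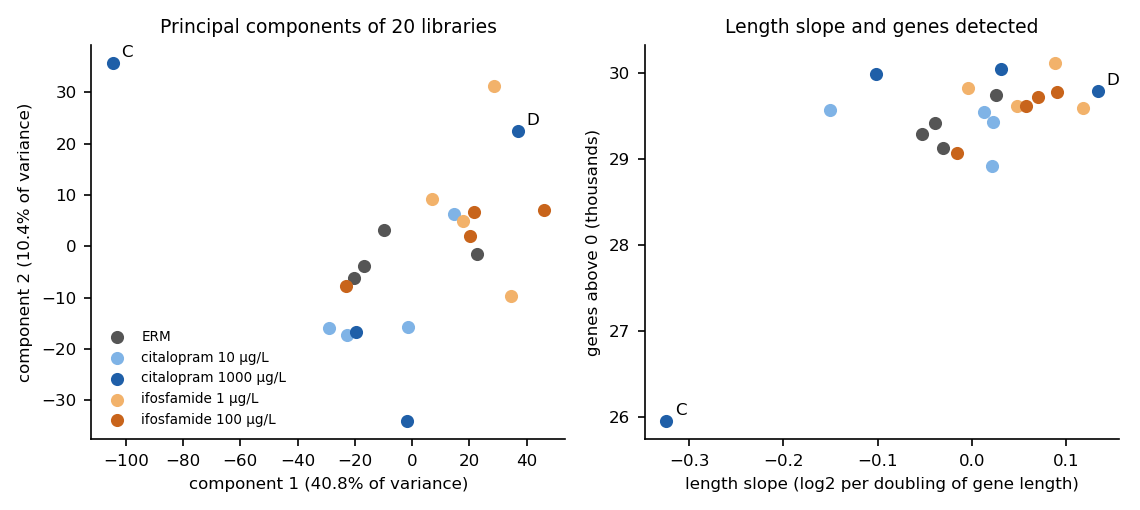
Left, the 20 libraries on the first 2 principal components of log2(FPKM + 1), which took up 40.8% and 10.4% of the variance; right, the slope of each library's signal on gene length (log2 per doubling) against its gene models above 0 (in units of 1000). Points are libraries coloured by group; library C of citalopram 1000 µg/L lies apart in both plots, with a length slope of -0.324 and 25952 gene models above 0.

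The comparison of citalopram 1000 µg/L with ERM asked what the high dose of this serotonin reuptake inhibitor did to gene expression in the larvae. 4 named genes of the sarcomere, the contractile unit of muscle, fell. The fast myosin heavy chain genes myhz1.3 (ENSDARG00000067997) and myhz2 (ENSDARG00000012944), which lie in a cluster of such genes on chromosome 5 and code for the motor protein of fast muscle, fell to less than 1/2 of their ERM level. The FPKM of myhz1.3 was 420 ± 18.6 in ERM and 177 ± 31.9 at the high dose (SD, n = 4 each), a log2 change of -1.26 (SE 0.18, limma adjusted p = 0.0164). The FPKM of myhz2 went from 1010 ± 76.7 to 493 ± 37.5 (-1.03, SE 0.15, adjusted p = 0.0164). The slow and cardiac-type myosin heavy chain gene myh7 (ENSDARG00000079564, chromosome 2) fell from 13.13 ± 1.54 to 6.82 ± 0.495 FPKM (-0.85, SE 0.13, adjusted p = 0.0164), and myom1a (ENSDARG00000061249, chromosome 2), which codes for a myomesin that cross-links thick filaments in the sarcomere, fell from 53.2 ± 1.93 to 27.4 ± 3.24 FPKM (-0.94, SE 0.16, adjusted p = 0.0395).

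In all, 6 of 19723 gene models passed the threshold at citalopram 1000 µg/L, 1 higher and 5 lower, while 1434 had an unadjusted p under 0.05 against 986 by chance. In each of the 6, the 4 exposed libraries lay wholly on one side of the 4 ERM libraries. Over all tested gene models this held for 3.68%, against 2.86% by chance. The fifth that fell was a gene model without an Ensembl identifier on the alternate contig CHR_ALT_CTG24_1_22 that the table describes as similar to a myosin heavy chain (-0.67, SE 0.11, adjusted p = 0.0437). The single rise was in si:ch211-226h7.5 (ENSDARG00000074150, chromosome 12, 46231498 to 46252062), from 2.97 ± 3.42 to 23.2 ± 14.1 FPKM (2.79, SE 0.48, adjusted p = 0.0456), and these last 2 were named after their values were seen. The count was 0 without library A or E of ERM, 3 without ERM B, 2 without library B of citalopram 1000 µg/L and 40 without its library D. Of the 6, 3 remained called without ERM C or library A of citalopram 1000 µg/L, and 4 without its library C. It was 0 when only these 8 libraries entered the model or when the replicate letter was added as a block, and voom on the recovered reads called 5.

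**Figure D2:**
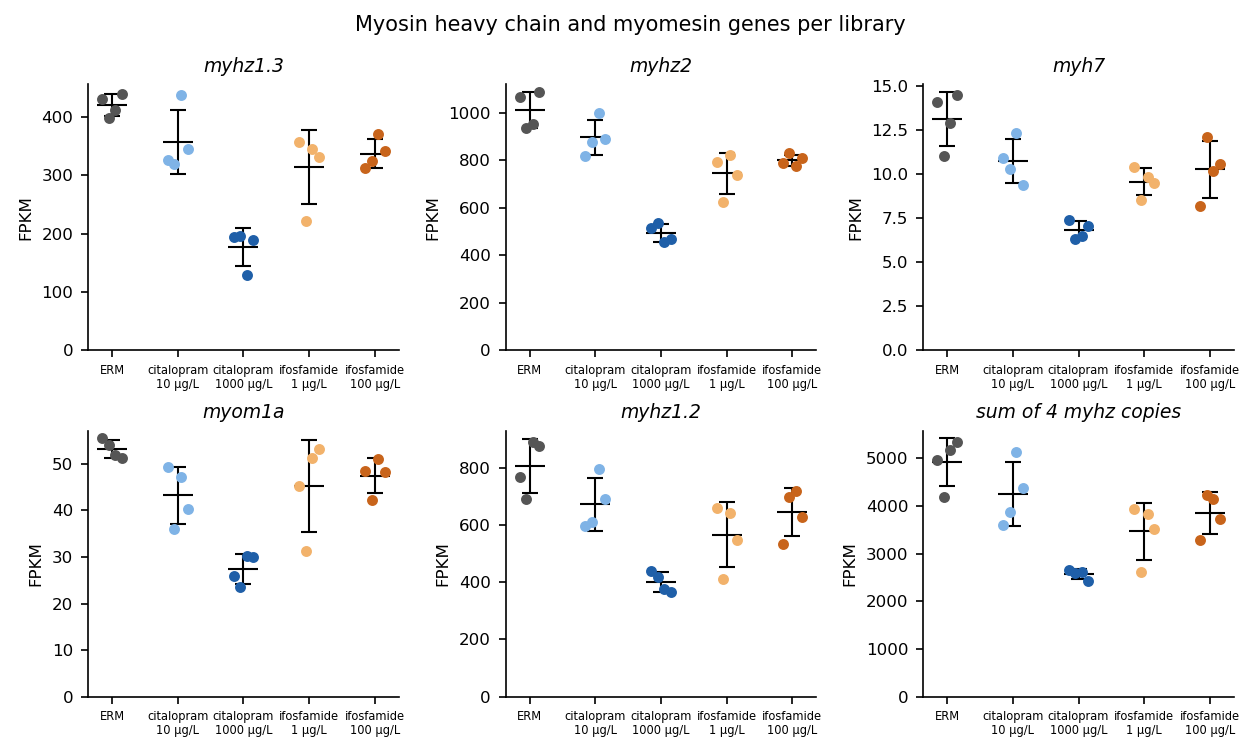
FPKM of myhz1.3, myhz2, myh7, myom1a and myhz1.2 and the summed FPKM of 4 fast myosin heavy chain copies on chromosome 5 (vertical axes, from 0) in the 5 groups. Points are libraries, long bars the means and whiskers the SD (n = 4); the summed FPKM was 4918 ± 507 in ERM and 2575 ± 104 at citalopram 1000 µg/L, with no overlap between these groups.

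As a list, skeletal muscle genes did not pass at citalopram 1000 µg/L (camera, adjusted p = 0.189 with an estimated correlation). Of its 106 tested members, 92 had a negative log2 change and the median was -0.29, against -0.32 at ifosfamide 1 µg/L. 3 members fell with p adjusted over all genes, and 28 fell and 0 rose with p adjusted over the list alone. Among those 28 were ttn.1 (titin, the spring of the sarcomere, -1.84, SE 0.39), nrap (-0.94, SE 0.19), the calcium channel subunit gene cacna1sb (-0.76, SE 0.15) and the fast alpha-actinin gene actn3b (-0.57, SE 0.14). None of these 4 passed over all genes, with adjusted p of 0.104, 0.0853, 0.0772 and 0.189. Of the other genes in the chromosome 5 cluster, none passed over all genes, with 807 ± 94.5 FPKM in ERM against 400.1 ± 34.6 for myhz1.2 (-1.01, adjusted p = 0.0583), 2680 ± 358 against 1504 ± 110 for myhz1.1 (-0.83, adjusted p = 0.228) and 19.6 ± 2.46 against 10.5 ± 1.17 for myhc4 (-0.84, adjusted p = 0.170). A second gene model named myhz1.1 (ENSDARG00000102414, chromosome 22) was at 21.1 ± 4.34 and 20.3 ± 1.68 FPKM (-0.04, adjusted p = 0.994). Light chain, actin and tropomyosin genes also did not pass, with mylz3 at 0.12, myl1 at -0.09, actc1b at -0.18 and tpma at -0.26 and adjusted p from 0.972 to 0.993. Library C of citalopram 1000 µg/L lay above the other 3 libraries in each of these 4, and without it the values were -0.29, -0.44, -0.51 and -0.67, with adjusted p from 0.542 to 0.777. Of 36 tested cardiac genes, 8 fell and 0 rose over the list alone, among them tnnt2d (-1.59, SE 0.29) and tnnt2a (-1.17, SE 0.24), which code for troponin T, and mybpc3 (-0.59, SE 0.13), which codes for a myosin-binding protein. The list median was -0.18.

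By camera with the correlation estimated from the data, 0 of 42 lists passed at citalopram 1000 µg/L. Both muscle lists had the smallest values, each with adjusted p = 0.189 with an estimated correlation. With the preset correlation, 11 lists passed, 9 up and 2 down, skeletal muscle (adjusted p = 2.1e-21) and cardiac genes (4.5e-05) among them, and none of the 11 held with an estimated correlation. The one-directional test of fry called 0 lists, and its test for change in either direction called both muscle lists, with adjusted p of 0.0014 for skeletal muscle and 7.7e-05 for cardiac genes. The median of skeletal muscle genes was -0.45 without library C and stayed negative under each scaling tried, and that of cardiac genes was -0.02 without library C.

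Outside muscle, none of the named genes passed over all genes at citalopram 1000 µg/L except si:ch211-226h7.5. The keratin gene krt93 went from 0.634 ± 0.801 to 6.82 ± 3.104 FPKM (95% interval of the log2 change 1.36 to 3.24, SE 0.45, adjusted p = 0.0772) and the transglutaminase gene tgm1l3 from 2.54 ± 2.59 to 20.1 ± 4.92 FPKM (2.80, SE 0.60, adjusted p = 0.113). Other positive values with the smallest p were those of cuzd1.1 (1.27), slc26a3.2 (0.98) and rgs2 (1.17), a regulator of G-protein signalling, with adjusted p from 0.104 to 0.172. In the interferon list, 6 of 32 members passed over the list alone and 0 over all genes. The immunoproteasome genes psmb8a (0.84) and psmb9a (0.85), tmem173 (0.88), which codes for the DNA-sensing adaptor STING, irf10 (0.70) and 1 of 2 gene models named irf1b (0.90) were higher, and irf7 was lower (-0.41). psmb9a passed over the proteasome list alone too. Its mean was 0.375 FPKM in ERM and 1.23 to 1.54 in the drug groups, so its difference was not particular to this dose. The list's median of 0.30 carried adjusted p = 0.644 with an estimated correlation. In library C alone, the interferon list had a median 0.67 above the other 3 libraries of its group, and the median against ERM was 0.11 without it. In the epidermis list, krt93, agr1 (0.86) and tgm1l4 (0.76) were higher and arg2 (-0.61) was lower over the list alone, and library C exceeded the others by a median of 0.88.

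Lens crystallins and lens structural genes had positive log2 changes for 51 of 52 members at citalopram 1000 µg/L, with a median of 0.73, 0 members past the threshold over the list alone and adjusted p = 0.644 with an estimated correlation. Library C exceeded the other 3 libraries by a median of 1.38 over this list, and the median against ERM was 0.34 without it. The lysosome list had a median of 0.22, which was 0.12 without library C, with adjusted p = 0.644 with an estimated correlation. Over the list alone, 1 member each passed for chgb (chromogranin B of secretory granules, -0.88), gys1 (muscle glycogen synthase, -0.64), neil1 (a DNA glycosylase of base excision repair, -0.77), chia.3 (an acidic chitinase of the gut, -0.98) and gstp2 (a glutathione S-transferase, 1.31).

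**Figure D3:**
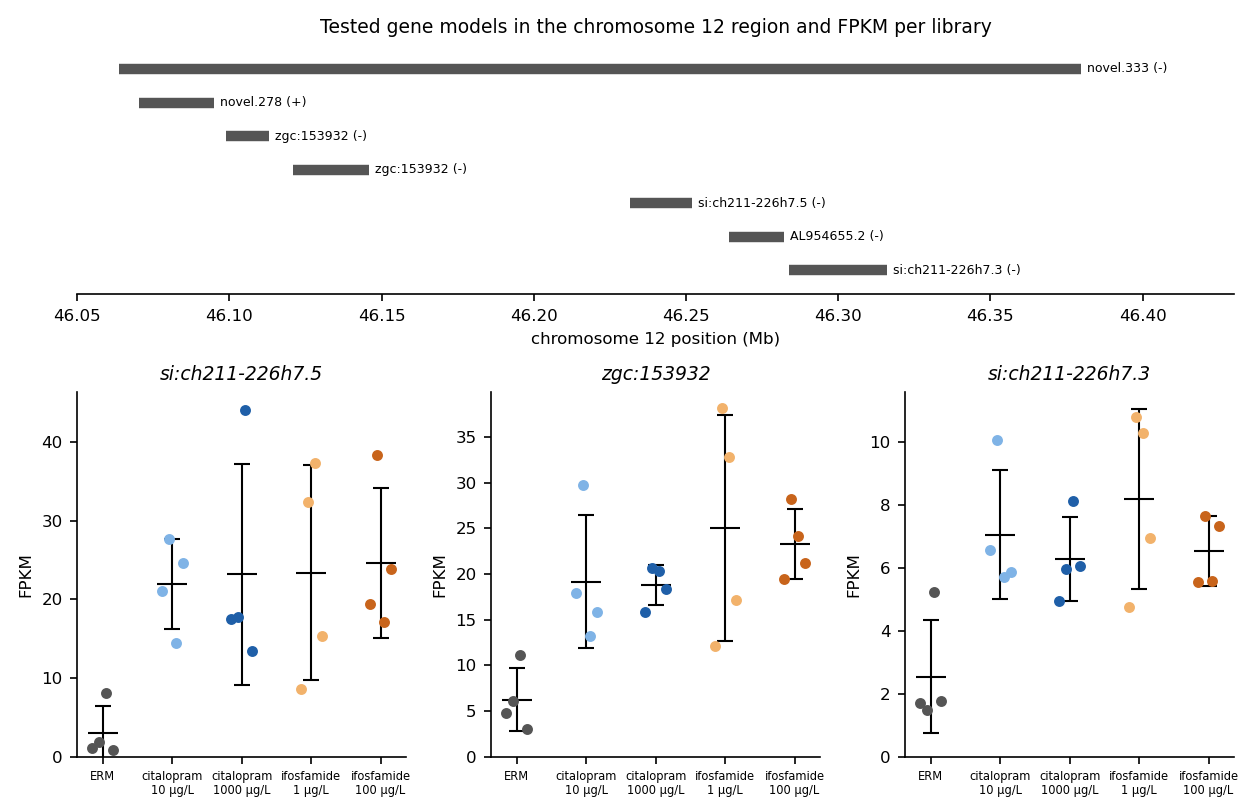
Tested gene models in a stretch of chromosome 12 that holds si:ch211-226h7.5, by position (Mb), and FPKM per library (vertical axes) of 3 of them in the 5 groups. Points are libraries, long bars the means and whiskers the SD (n = 4); the FPKM of si:ch211-226h7.5 was 0.854 to 8.06 in ERM and 8.56 to 44.1 in the 16 drug libraries, and the stretch was chosen after its values were seen.

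**Figure D4:**
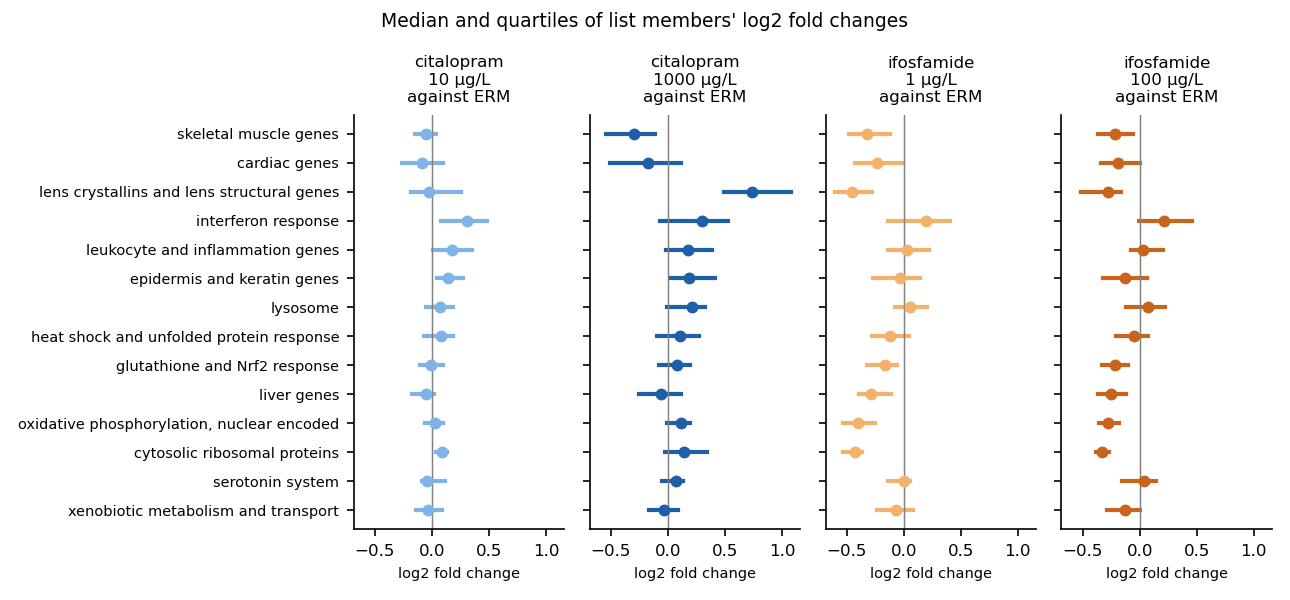
Median (points) and quartiles (bars) of the log2 fold changes of the tested members of 14 gene lists, for each drug dose against ERM. At citalopram 1000 µg/L the skeletal muscle median is -0.29 and the lens median 0.73 (0.34 without its library C); at ifosfamide 1 µg/L the median of cytosolic ribosomal proteins is -0.42; camera with an estimated correlation called 0 lists in each panel.

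At citalopram 10 µg/L, 2 of 19723 gene models passed the threshold against ERM, both higher. They were CABZ01114318.1 (ENSDARG00000099702, chromosome 24), from 3.33 ± 1.00 to 8.06 ± 1.59 FPKM (SD, n = 4; 1.08, SE 0.16, adjusted p = 0.0257), and a gene model without an Ensembl identifier on the contig KN150521.1 (15002 to 20896), from 2.47 ± 0.152 to 11.5 ± 3.52 FPKM (1.80, SE 0.27, adjusted p = 0.0257). Both were named after their values were seen. Among named genes, polr1d, which codes for a subunit of RNA polymerases I and III, had the smallest p, with 7.02 ± 0.757 FPKM in ERM and 0.390 ± 0.244 at the low dose (-2.54, SE 0.47, adjusted p = 0.154). It passed in 3 of 23 alternatives, among them the model of only these 8 libraries (adjusted p = 0.000216), which called 2 gene models, 1 of them shared. All 16 drug libraries lay below the 4 ERM libraries in polr1d, with means of 2.503 FPKM at citalopram 1000 µg/L, 2.38 at ifosfamide 1 µg/L and 1.64 at 100 µg/L. The cerebellin gene cbln12 had -1.07 (adjusted p = 0.432), and krt96 (1.51), rgs2 (1.02), ms4a17a.10 (1.02), nox1 (0.66) and ctgfb (0.50) had positive values with adjusted p of 1.00. The count was 0 without any of ERM A, ERM E or libraries A, B and D of citalopram 10 µg/L, 1 without ERM B or library C of the low dose, and 0 by voom or with the replicate letter as a block. Without ERM C it was 2, of which 0 were shared with these 2 gene models, and each of them was called in 1 of the 8 models that left out 1 library. At an unadjusted p under 0.05 there were 478 gene models, against 986 by chance.

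Of the 42 lists, 0 passed at citalopram 10 µg/L with an estimated correlation, and 9 passed with the preset correlation. The smallest adjusted p belonged to the interferon list, in which 27 of 32 members had positive values, with a median of 0.31, a preset adjusted p of 6.9e-10 and adjusted p = 0.738 with an estimated correlation. The leukocyte list had a median of 0.17 and the epidermis list 0.14, each with adjusted p = 0.957 with an estimated correlation. Skeletal muscle genes had a median of -0.06.

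The comparison of the citalopram doses asked whether the high dose differed from the low one. limma called 0 of 19723 gene models, with 723 at an unadjusted p under 0.05 against 986 by chance, and voom called 0. The smallest p belonged to the same myosins, myhz1.3 with 357 ± 54.5 FPKM at 10 µg/L and 177 ± 31.9 at 1000 µg/L (-1.02, SE 0.18, adjusted p = 0.215) and myhz2 with 896 ± 75.5 and 493 ± 37.5 (-0.86, SE 0.15, adjusted p = 0.215). myh7 had -0.58, myom1a -0.63 and tnnt2d -1.26. Over the list alone 13 skeletal muscle genes and 6 cardiac genes were lower at the high dose and 0 were higher, and both lists had adjusted p = 0.297 with an estimated correlation. The summed FPKM of the 4 myhz copies on chromosome 5, a sum chosen after their values were seen, was 4249 ± 674 at 10 µg/L, 2575 ± 104 at 1000 µg/L and 4918 ± 507 in ERM.

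The genes fixed for citalopram showed no change past the threshold. The serotonin transporter gene slc6a4a, whose product the drug blocks, was at 5.54 ± 0.566 FPKM in ERM, 5.195 ± 1.21 at 10 µg/L and 4.16 ± 1.85 at 1000 µg/L (-0.44, 95% interval -1.02 to 0.14, and -0.11 without library C of that dose). tph2, for the rate-limiting enzyme of serotonin synthesis, had -0.30 and -0.29 at the 2 doses, and mao, for monoamine oxidase, -0.08 and 0.17. slc6a4b lay below the filter, with a mean of 0.460 FPKM. Of 15 tested members of the serotonin list, 0 passed at either dose over the list alone. In the stress axis, pomca, for the precursor of the hormone ACTH, was at 0.589 ± 0.426 FPKM in ERM and 2.97 ± 1.47 at the high dose (1.28, SE 0.37, adjusted p = 0.292), and crhb (0.37), nr3c1 (-0.12) and fkbp5 (0.06) had intervals that included 0. In crhb, library C of the high dose was at 13.2 FPKM against 4.66 to 9.23 in the rest of its group. Over the alternatives the crhb value ranged from 0.17 to 0.61. The xenobiotic-inducible cytochrome gene cyp1a was at 21.6 ± 1.46 FPKM in ERM, 34.4 ± 7.21 at 10 µg/L (0.62, adjusted p = 1.00) and 36.5 ± 13.4 at 1000 µg/L (0.67, adjusted p = 0.292), and both citalopram groups lay above ERM in every library. cyp3a65 had 0.13 and 0.01, and the haem oxygenase gene hmox1a had 0.53 and 0.69. At 10 µg/L, hmox1a was highest in library B (26.5 FPKM against 5.06 to 12.8 in the rest of the group). At 1000 µg/L it was highest in library C (27.2 against 5.21 to 17.6). Over the alternatives its log2 change ranged from 0.15 to 0.87 at 10 µg/L and from 0.35 to 1.07 at 1000 µg/L. gstp1.1 was not analysed here.

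The comparison of ifosfamide 1 µg/L with ERM asked what a low dose of this DNA-alkylating drug did. limma called 0 of 19723 gene models, with 946 at an unadjusted p under 0.05 against 986 by chance and a smallest adjusted p of 0.112, and voom called 0. The smallest p among named genes belonged to hsp70l, an inducible heat shock gene, followed by the peroxiredoxin gene prdx1 (-0.75) and the heat shock genes hsp70.3 and hsp90aa1.2. hsp70l was at 9.33 ± 6.22 FPKM in ERM and 1.03 ± 0.394 at 1 µg/L (-2.14, SE 0.48, adjusted p = 0.603), hsp70.3 at 20.1 ± 15.96 and 1.37 ± 0.353 (-2.75, SE 0.69) and the chaperone gene hsp90aa1.2 at 21.5 ± 3.83 and 12.7 ± 0.835 (-0.70, SE 0.18). The embryonic alpha-globin gene hbae3 (-1.09) had a value of the same sign, and each of these 5 had its 4 exposed libraries below the 4 ERM libraries. Over all tested gene models, 1377 (6.98%) had no overlap between these groups in either direction, against 2.86% by chance. On the other side stood sult5a1 (1.74), a sulfotransferase gene, plekhs1 (1.75), mpeg1.2 (1.59), a perforin-like macrophage gene, adgrf8 (1.02) and b3gnt7 (0.69). The count was 4 without ERM C and 5 without library A of ifosfamide 1 µg/L.

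Over the list alone, 6 of 65 heat shock and unfolded protein response genes were lower at ifosfamide 1 µg/L, namely hsp70.1, hsp70.2, hsp70.3, hsp70l, hsp90aa1.2 and hspb1, and 0 were higher. The list's median of -0.12 carried adjusted p = 0.619 with an estimated correlation and turned to 0.03 when libraries were scaled to total reads. Over their own lists, prdx1 and hbae3 were lower as well. Of 81 cytosolic ribosomal protein genes, 81 were negative with a median of -0.42, and of 80 nuclear genes of oxidative phosphorylation 77 were negative with a median of -0.40. Of 87 liver genes, 77 were negative with a median of -0.28, and skeletal muscle genes had a median of -0.32. The adjusted p with an estimated correlation was 0.619 for the first 3 of these lists and 0.401 for skeletal muscle. With the preset correlation 22 lists passed, 18 of them down, and 0 held with an estimated correlation. Scaling to total reads moved the median of all genes from -0.0069 to 0.13 and left the medians of these 4 lists negative. The slope of signal on gene length had a mean of 0.0625 at ifosfamide 1 µg/L and -0.0239 in ERM (log2 per doubling), and with that slope as a covariate the median was -0.02 for cytosolic ribosomal proteins, -0.09 for oxidative phosphorylation, nuclear encoded, -0.11 for liver genes and -0.19 for skeletal muscle genes.

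At ifosfamide 100 µg/L, limma called 0 of 19723 gene models against ERM, with 644 at an unadjusted p under 0.05 against 986 by chance and a smallest adjusted p of 0.0764, and voom called 0. Keratin gene krt96 was at 6.55 ± 3.84 FPKM in ERM and 28.4 ± 10.07 at 100 µg/L (2.03, SE 0.44, adjusted p = 0.430), and it passed over the epidermis list alone. In the other drug groups its mean was 16.1 to 20.6 FPKM. mrpl54 (1.43), psme2 (0.77), sult5a1 (1.67) and vwa10.1 (1.21) had the next smallest p among positive values. Genes of liver metabolism stood among the negative values, namely cyp8b1, for sterol 12-alpha-hydroxylase of bile acid synthesis, at 10.6 ± 0.903 and 5.86 ± 2.04 FPKM (-0.81, SE 0.20, adjusted p = 0.859), uroc1, for urocanase of histidine breakdown (-0.53, SE 0.13), and agxtb, for an alanine-glyoxylate aminotransferase, at 145 ± 27.3 and 85.5 ± 12.5 FPKM (-0.75, SE 0.20). polr1d (-1.87) and sh2d3cb (-0.58) completed the set. The count was 5 without ERM C and 2 with a filter at a mean FPKM of 5.

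Of the 42 lists, 0 passed at ifosfamide 100 µg/L with an estimated correlation, and 24 passed with the preset correlation, 19 of them down. The smallest adjusted p with an estimated correlation was 0.233, shared by fatty acid oxidation, in which 42 of 50 members were negative with a median of -0.20, and by gluconeogenesis, glycolysis and insulin response, with 46 of 69 negative and a median of -0.20. Of 87 liver genes, 80 were negative with a median of -0.25 (adjusted p = 0.372 with an estimated correlation), and the interferon list had a median of 0.22 (0.340). The slope of signal on gene length had a mean of 0.0506 at ifosfamide 100 µg/L and -0.0239 in ERM (log2 per doubling), and with that slope as a covariate the median was -0.13 for liver genes and 0.32 for interferon response. The summed FPKM of the 4 myhz copies was 3474 ± 596 at ifosfamide 1 µg/L, with no overlap with ERM, and 3850 ± 435 at 100 µg/L.

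Between the ifosfamide doses, limma called 0 of 19723 gene models, with 168 at an unadjusted p under 0.05 against 986 by chance, a smallest adjusted p of 1.00 and 0 calls by voom. The smallest p among named genes belonged to mrpl54, for a mitochondrial ribosomal protein, with 1.49 ± 0.681 FPKM at 1 µg/L and 7.02 ± 2.72 at 100 µg/L (1.66, SE 0.36), and to mmp25b, for a matrix metalloproteinase, with 1.44 ± 0.316 and 0.643 ± 0.126 (-0.57, SE 0.15). The kidney and heart transcription factor gene wt1a (-0.54), ugt1b1 (-0.55), wnt2ba (-0.45) and a mitochondrial gene model (-1.19) had negative values, and ubxn6 (0.80), ecd (0.45), uspl1 (0.53) and tbc1d7 (0.33) positive values, all without passing. 0 of 42 lists passed with an estimated correlation and 7 with the preset correlation, the smallest adjusted p being 0.728 with an estimated correlation.

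Genes fixed for ifosfamide, which respond to DNA damage or take part in the cell cycle, did not pass the threshold at either dose. The cell cycle inhibitor gene cdkn1a had -0.27 (95% interval -0.70 to 0.15) and -0.08 (-0.51 to 0.34) at the 2 doses, mdm2 -0.07 and -0.33 (-0.62 to -0.04, adjusted p = 0.920), ccng1 -0.04 and -0.22, pcna -0.23 and -0.18, and gadd45aa -0.30 and -0.15. cyp1a had -0.01 and -0.06, cyp3a65 -0.39 and -0.45, and hmox1a 0.27 and 0.18. In cyp3a65, library C of ifosfamide 100 µg/L was at 298 FPKM against 523 to 869 in the rest of its group.

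The F-test over all 4 comparisons with ERM called 0 of 19723 gene models in limma, with 1139 at an unadjusted p under 0.05 and a smallest adjusted p of 0.121, and 0 by voom. It called 25 without library D of citalopram 1000 µg/L, 2 without library B of ifosfamide 1 µg/L and 1 without ERM C or library A of ifosfamide 1 µg/L. Across genes, which are not independent replicates, the changes at the 2 ifosfamide doses correlated at Pearson r = 0.80 and Spearman rho = 0.79, and those at the 2 citalopram doses at 0.57 and 0.51. The pairs across drugs ranged from 0.15 to 0.38. All of these share the 4 ERM libraries. 1000 simulations of unchanged groups against a shared reference gave a mean r of 0.47 (95% range -0.24 to 0.89), and none of the 6 values lay outside that range. With the ERM libraries split 2 and 2 between the comparisons, r was 0.41 for the ifosfamide doses and 0.16 for the citalopram doses, while simulations of unchanged groups split in this way gave a mean of 0.0153 (95% range -0.68 to 0.69), so that neither lay outside that range. No gene was called in both members of any pair.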

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

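The tests of depth and of a swapped label for library C of citalopram 1000 µg/L and of a region on chromosome 12 were chosen only after the results were seen. Within a group of 4, a library is named here when its gap to the nearest other library takes up so much of the group's whole range that chance flags about 1 in 20 groups. Among library measures 3 of 40 groups had such a library against 2 by chance, and among named genes 15 of 197 groups against 9.85 by chance.

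In library C of citalopram 1000 µg/L, the number of gene models above 0 (25952 against 29790 to 30045 in the other 3) gave a gap of 0.938 of the range, and the share of reads in the 10 largest genes (13.3% against 9.47% to 10.08%) a gap of 0.841. In the same library krt93 was high (11.5 against 4.95 to 5.54 FPKM, 0.910), myhz1.3 low (129 against 190 to 196, 0.908) and slc6a4a low (1.42 against 4.74 to 5.41, 0.832). The deviation of library C from the other 3 libraries had an SD over genes of 0.865, and of 0.824 once the gene-length trend was removed. This argues against that trend as the whole difference. The trend took up 9.42% of the variance of the deviation, but no library had a share above 10.6%. This share therefore measures length effects weakly. Over all libraries, the first principal component correlated with the length slope at 0.931, so a length-related part is not excluded. The tables argue against low depth, since 14 other libraries had fewer recovered reads. A label swapped between library C and citalopram 10 µg/L, the closest other group, cannot be judged by correlations. The mean correlation of library C with that group was 0.907, which is -0.0498 from the lowest value of a library of that group with its own (0.957). Of those 4 libraries, 0 were closest to the rest of citalopram 1000 µg/L. However, library C lay at 0.868 to 0.907 with every group. Libraries A, C and D of citalopram 10 µg/L also had higher mean correlations with another group (0.968, 0.966 and 0.960) than with their own (0.957, 0.958 and 0.958). Ribosomal protein genes (median 1.63 above the other 3 libraries), lens genes (1.38) and exocrine pancreas genes (1.24) were high in library C. A degraded sample that passed the RNA quality limit named in the labels, a wrong label or a different response of that beaker stay open. No biological explanation was tested.

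The gene si:ch211-226h7.5 was high in library C of citalopram 1000 µg/L (44.1 against 13.5 to 17.8 FPKM, 0.859) and in ERM C (8.06 against 0.854 to 1.92, 0.852). It belongs to a set of 5 gene models that lay below the mean of the 4 drug groups in ERM, with log2 differences of -2.82 for this gene (SE 0.38, limma adjusted p = 0.0047), -1.69 for zgc:153932 (ENSDARG00000052779, 0.0205), -1.25 for si:ch211-226h7.3 (0.0468), -1.45 for a gene model without an Ensembl identifier on chromosome 12 (0.0307) and -1.62 for the gene model on KN150521.1 (0.0047), while 711 had an unadjusted p under 0.05 against 986 by chance. Of the 5, 4 lie between 46063858 and 46379704 on chromosome 12, and the one without an Ensembl identifier spans the others there. All 7 tested gene models of that stretch, which was chosen for these 4, had lower values in ERM.

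Of 100 sets of 4 libraries, ERM included, 3 gave as many genes against the other 16 as ERM (5). That share is not adjusted for the 5 groups tried, so chance is not excluded. The highest other set gave 3276, far more than ERM, and what that set followed was not tested. Against the other 4 groups, citalopram 1000 µg/L gave 23 genes, so that ERM is not alone in standing apart, and the other drug groups gave 0. Handling of the ERM beakers apart from the exposed ones cannot be told apart from the absence of drug, because the labels name no batch. A sequence variant or a parental difference in that stretch of chromosome 12, where 4 of the 5 lie, cannot be told apart from shared regulation of neighbouring genes, because the table holds no sequence.

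[figure]
In the remaining groups 1 library stood apart and no explanation was tested. At citalopram 10 µg/L these were library C by its length slope (-0.151 against 0.0125 to 0.0224, 0.943) and library A by rgs2 (15.9 against 6.71 to 8.18 FPKM, 0.840) and ccdc136b (11.2 against 8.62 to 9.06, 0.831). In ERM they were library A by hmox1a (13.05 against 5.92 to 7.00, 0.849), library C by mpeg1.2 (18.8 against 5.41 to 7.52, 0.842) and library E by cyp8b1 (11.9 against 9.996 to 10.27, 0.858). At citalopram 1000 µg/L library B stood apart by tgm1l3 (27.5 against 17.1 to 18.5, 0.869). In ifosfamide, library A of 1 µg/L stood apart by ubxn6 (1.68 against 2.02 to 2.08, 0.853) and tbc1d7 (18.1 against 22.4 to 23.2, 0.835), and wt1a set apart library B of 1 µg/L (2.23 against 1.66 to 1.75, 0.843) and library B of 100 µg/L (0.531 against 1.05 to 1.12, 0.884).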

How the results depend on the processing

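The alternatives voom, scaling to total reads, both length corrections the model without library C of citalopram 1000 µg/L and the share of counting noise were chosen only after the results were seen. Of 110 alternative gene counts, 78 stayed within 1.5 times the main count and 32 moved; of 54 list counts, 42 stayed and 12 moved; of 12 correlations, 8 stayed within 1 SD of the simulated values (0.291) and 4 moved by more. Of 3782 alternative values of named genes, 190 belonged to called genes, of which 119 kept the call and 71 lost it, and 0 changed sign; of the 3592 values of uncalled genes, 49 gained a call and 169 changed sign. Where a value moved, the cause was not tested, except that fewer genes or libraries entered some models by construction. For citalopram 10 µg/L the count of 2 was 0 without a filter, with the replicate block and by voom, 1 in protein-coding genes, 4 without library C of citalopram 1000 µg/L, 5 with the length slope as a covariate and 5 with array weights. For citalopram 1000 µg/L the count of 6 was 15 with a filter at 5 FPKM, 16 after quantile normalization, 0 with only the 2 groups in the model, 0 with the replicate block, 3 with a minimum change of 1, 3 after the length trend was removed, 69 with the length slope as a covariate and 3879 with array weights. Array weights, which gave a convergence warning, called 188 for ifosfamide 1 µg/L, 209 for 100 µg/L, 1009 between the citalopram doses and 9153 in the F-test. For ifosfamide 1 µg/L the count of 0 was 1 after quantile normalization. For ifosfamide 100 µg/L it was 2 with a filter at 5 FPKM, with centring, with total-read scaling and without library C of citalopram 1000 µg/L, and 1 without a filter, after quantile normalization and with only the 2 groups. Without a filter it was 2 between the ifosfamide doses, and the length covariate gave 1 between the citalopram doses. The F-test called 4 with a filter at 5 FPKM, 2 without a filter and 4 with the length covariate. With each library left out, counts ranged from 0 to 2 for citalopram 10 µg/L, 0 to 40 for 1000 µg/L, 0 to 5 for each ifosfamide dose and 0 to 25 in the F-test, and stayed at 0 between doses. The list counts of 0 were 9, 11, 22, 24, 8 and 7 with the preset correlation, in the order of the comparisons. They were 1 at citalopram 1000 µg/L and between its doses after quantile normalization and total-read scaling, 2 at ifosfamide 100 µg/L with total-read scaling, and 1 between the citalopram doses with the length covariate. They stayed at 0 with each library left out and by the directional test of fry. With the ERM libraries split, r was 0.16 for the citalopram doses, -0.0139 for citalopram 10 with ifosfamide 1 µg/L, 0.0265 for citalopram 10 with ifosfamide 100 µg/L and 0.41 for the ifosfamide doses. It changed sign within that SD for citalopram 1000 with ifosfamide 1 µg/L (0.148 to -0.0511) and with ifosfamide 100 µg/L (0.219 to -0.0205). Replicate letters gave no clear sign of pairing, since 6 of 20 libraries correlated best with a library of their own letter outside their group. The mean residual correlation between groups was 0.0201 for libraries of the same letter and -0.00583 for other letters. Single same-letter pairs reached 0.424, and what the letters mark is not stated, so a pairing is not excluded. Counting of reads took up a median of 19.8% of the residual variance in tested genes with a mean of 1 to 2 FPKM and 0.255% from 100 FPKM up, so other variation between libraries, of beakers or of their preparation, was the larger part at both ends.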

Other observations

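The test of each group against the mean of the other 4, the summed myosins, the length match, the shared reads and the muscle share without library C were chosen only after the results were seen. Against the other 4 groups, limma called 23 gene models for citalopram 1000 µg/L, 5 higher and 18 lower, with 2123 at an unadjusted p under 0.05, and 5 for ERM, all lower. It called 0 for citalopram 10 µg/L, ifosfamide 1 µg/L and ifosfamide 100 µg/L, with 565, 1226 and 517 at an unadjusted p under 0.05, and no other tool was run on these.

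The fall of myosin heavy chain and myomesin genes at citalopram 1000 µg/L rests on 5 calls. A gene-length bias common to all genes is argued against by 1201 other protein-coding genes within 10% of the lengths of the 5 that fell. Their median change was -0.0321 (quartiles -0.15 and 0.08), against -0.94 for those that fell. These genes come from all tissues, so they cannot exclude a length pattern among muscle genes. Removing the length trend lowered the count of calls and the length slope as a covariate raised it, as given above. Over all alternatives the log2 change stayed between -1.35 and -1.12 for myhz1.3 and between -1.12 and -0.99 for myhz2. The calls were less stable. Of 24 alternatives, myhz1.3 was called in 20, myhz2 in 19, myh7 in 17 and myom1a in 14. The gene model without an Ensembl identifier was called in 11 of 23. Reads shared between near-identical copies are argued against by the summed FPKM of the 4 myhz copies on chromosome 5, which fell by 0.93 on the log2 scale with no overlap between groups and also lay lower without overlap at ifosfamide 1 µg/L (-0.51). A smaller share of muscle in the larvae cannot be told apart, because 26 of 79 other skeletal muscle genes with a mean FPKM of at least 5 had 95% intervals above the smallest fall of the 5 (-0.67), too many for that explanation and too few to exclude it by the bounds set before, while 52 lay above the smallest fall of the called list members (-0.94) and, without library C of citalopram 1000 µg/L, 14 lay above the smallest fall of the 5 (-0.66). A smaller share of muscle, a lower output of some sarcomere genes and a delay in muscle maturation stay open, and the last 2 were not tested.

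Other splits of the same libraries were run through the same model. For citalopram 1000 µg/L, 1 of 35 splits, the real one, gave as many as 6 genes and the highest other gave 2. That share, 0.0286, is the smallest that 35 splits can give. It is not adjusted over the 6 comparisons, so chance is not excluded. The count of 6 was 0 with the replicate block and with only the 2 groups in the model. For citalopram 10 µg/L, 1 of 35 gave as many as 2 and the highest other gave 1. A margin of 1 gene is narrow, and the count was 0 with the replicate block, by voom and without a filter. Chance is not excluded here either. For ifosfamide 1 µg/L, ifosfamide 100 µg/L and the ifosfamide doses, the real count was 0 and the highest other was 0, and since every split (35 of 35) reaches 0 by construction the test says nothing about chance. Between the citalopram doses the real count was 0 and the highest other was 61. Another grouping of these libraries thus set apart more genes than the doses did. That split joined library D of citalopram 1000 µg/L with libraries A, B and D of citalopram 10 µg/L. The next highest, with 47, joined it with libraries A, B and C of citalopram 10 µg/L. Why library D of citalopram 1000 µg/L grouped in this way was not tested. For the lists, the real count was 0 in every comparison, all 35 splits reach that by construction, which says nothing about chance, and the highest other was 1 for ifosfamide 1 µg/L and for the citalopram doses and 0 elsewhere. For the F-test, the real count was 0, which all 100 regroupings reach by construction, so that this test too says nothing about chance, and the highest other gave 1.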
